A study of Arabidopsis thaliana with 6 samples.

How the data were processed

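Small RNA libraries were made from pollen of Arabidopsis thaliana, 3 from wild-type and 3 from paps1-3 grains, with a TruSeq small RNA kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Whole RNA was extracted from sorted grains, and both genotypes of an isolation came out of one sample, per the labels' protocols. No label says which wild-type library shares an isolation with which mutant library, or that isolations came from separate plants, so p-values measure the spread between these samples, which may be technical. Genotype and sort gate are one and the same split.

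The deposited files hold whole counts of reads per annotated segment, not normalised, with 1 column for each read length from 18 to 28 nt, per the file headers. Reads were processed with Trimmomatic, BWA, SAMtools and bedtools against TAIR10, per the submitters' processing notes, which give no versions. How reads that map to several places and strand were treated is not given in the sources used here. This matters for rRNA, tRNA, miRNA families, transposons and mitochondrial sequences with nuclear copies, since a read may be counted at each copy or at one of them. Every library listed the same 176473 segments under 60936 IDs, of which 30245 were transposons, 137 mitochondrial and 129 chloroplast features. Segments covered by several genes carry joined IDs (2043 IDs, 1.68% of counts) and were kept as features of their own.

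Counts were summed per ID over segments. Gene names, biotypes and products came from the RefSeq annotation of TAIR10.1, which matched 27975 of 28395 nuclear gene IDs, and no coordinates were taken from it. Transposon and organelle IDs have no names there. Transposon superfamilies, Athila elements and the split into chromosome arms and pericentromeres were planned and not run, because no annotation naming them was used here.

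Changes per feature were tested with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood test, with TMM factors, filterByExpr on the genotype, no block and Benjamini-Hochberg adjustment at 0.05, over all lengths together and separately at 21, 22 and 24 nt. TMM factors were 1.12, 1.38 and 1.53 in wild type and 0.546, 0.870 and 0.893 in paps1-3, so the choice of scaling sets where zero change lies. Lists of genes were tested with camera of limma 3.58.1 on log-CPM with a preset correlation of 0.01, and again with an estimated one. The 9 lists run were leaf photosynthesis, tapetum, vegetative-cell, sperm-cell, TAS, small RNA pathway, PAPS, miRNA and miR845 genes. Class shares and the counts of PAPS1 were compared with exact two-sided permutation tests over the 20 assignments of libraries to genotypes, whose smallest p is 0.1. The interval of the PAPS1 rate ratio is an exact conditional binomial one. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, exact tests and figures.

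The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took PAPS1; the 12 features with the largest increase and the 12 with the largest decrease among those called, with a mean of at least 5 CPM and no overlap of libraries; and from each list the 3 members with the smallest p and the one with most reads. Genes outside the rule are said to be chosen after their values were seen.

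Whether adjacent library numbers mark an isolation was checked by the correlation, across features, of deviations from the genotype means. Libraries 15 and 16, 19 and 20, and 25 and 26 had r of 0.40, 0.24 and 0.23, and other pairs −0.29 to 0.12. All 3 adjacent pairs were above the minimum of 0.1 and were therefore taken as the isolations for the blocked fit, an alternative to the fit without block.

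Tested on simulated data with 200 changed features, the edgeR step recovered 21% of 2-fold and 93% of 4-fold changes over all lengths, with 1.72% of calls false. At 21 nt it recovered 21% and 97% with 2.48% false, at 22 nt 35% and 94% with 3.73% false, and at 24 nt 61% and 100% with 7.47% false. Changes near 2-fold were thus often missed in the simulation. Its changed features were drawn from those with more counts, as many up as down, and the libraries were otherwise given the same composition. The real libraries had unequal TMM factors and more higher than lower calls, so these rates may not carry over to them.

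The alternatives were DESeq2 1.42.0, limma-trend with a prior count of 2, RLE factors, total-read scaling, scaling to miRNA loci, no count filter, a stricter one (10 counts in 3 libraries and a mean of 1 CPM), removal of structural and organellar features, the block, and each library left out in turn. Added after seeing the data were the fit to single segments, the fit without libraries 15 and 16, and class shares without mitochondrial reads.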

Results

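Small RNAs of mature Arabidopsis thaliana pollen (accession Col) were sequenced from wild-type grains and from grains carrying paps1-3, a mutant allele of PAPS1, which encodes a nuclear poly(A) polymerase. Each genotype had 3 libraries, numbered 15, 19 and 25 for the wild type and 16, 20 and 26 for paps1-3. Grains of both genotypes were sorted out of the same sample, in 3 such isolations. Reads of 18 to 28 nt were counted on annotated genes and transposons. The wild-type libraries held 10139424, 9757853 and 9312167 counted reads, and the paps1-3 libraries 7916557, 5562287 and 9922763. The series asks how PAPS1 relates to RNA-directed DNA methylation, the pathway in which 24-nt small RNAs guide methylation to transposons. Between 45277 and 47947 features had reads in a wild-type library, against 33984 to 39927 in a paps1-3 library. On the first principal component of the tested features, with 56.6% of the variance, the genotypes separated, and the second, with 20.3%, set wild-type 15 and paps1-3 16 apart from the other libraries.

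PAPS1 itself (AT1G17980) had few small RNA reads. The wild-type libraries held 7, 4 and 4 reads and the paps1-3 libraries 0, 0 and 1. The ratio of read rates, paps1-3 over wild type, was 0.0832 with an exact 95% interval of 0.00198 to 0.541, which covers counting error only. Rates were per counted read, a scale on which 5426 tested features were called lower and 811 higher (edgeR). The ratio thus does not show that PAPS1 reads fell more than those of other features. With edgeR, TMM and no count filter PAPS1 had a log2 fold change of −2.56 (SE 1.21, edgeR adjusted p = 0.306). TMM-scaled CPM values were 0.405 ± 0.192 and 0.0380 ± 0.0657 (SD, n = 3 each, exact permutation p = 0.1, the smallest that 3 libraries against 3 allow). Small RNA reads do not measure the messenger RNA, so this is a weak check of the genotype labels.

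The makeup of the small RNA pool differed between the genotypes. Transposon reads were 9.32% ± 0.449 of all counted reads in wild type and 4.90% ± 0.583 in paps1-3 (SD, n = 3 each), a ratio of 0.526. Reads on miRNA loci were 3.14% ± 0.558 and 1.39% ± 0.199, a ratio of 0.443. Reads on TAS loci, the precursors of trans-acting siRNAs, were 0.125% ± 0.0644 and 0.0358% ± 0.00745, a ratio of 0.287. This class leaves out TAS1C, whose segment is shared with AT2G39670 and was classed with the overlapping genes. That segment had 7836, 17687 and 23037 reads in wild type and 3636, 2554 and 5842 in paps1-3. Mitochondrial features went the other way, from 4.95% ± 0.882 to 15.6% ± 2.70, a ratio of 3.15. Of that gap of 10.6 percentage points, 8.38 came from the single feature ATMG00020 (1.41% ± 0.561 and 9.79% ± 1.45), and without it the mitochondrial ratio was 1.63. Organelle feature IDs were not paired with gene names in the annotation used here. snoRNA reads, from the guides of rRNA modification, were 0.0501% ± 0.00352 and 0.117% ± 0.0250.

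Protein-coding genes held 9.27% ± 0.428 of reads in wild type and 6.61% ± 0.926 in paps1-3, and chloroplast features 0.905% ± 0.0758 and 0.568% ± 0.141 (SD, n = 3 each). Pseudogenes held 2.80% ± 0.272 and 1.04% ± 0.350, mostly on AT2G07731, whose counts nearly equalled those of the mitochondrial ATMG00270, so the reads cannot be assigned to either. Without AT2G07731 the pseudogene ratio moved from 0.370 to 0.655 and the libraries overlapped (exact permutation p = 0.2). In each of these 8 classes, taken whole, the libraries of the genotypes did not overlap, and the exact two-sided permutation test gave p = 0.1, the lowest it can give (Benjamini-Hochberg 0.163 over 13 classes). rRNA made up 55.4% ± 2.77 and 55.2% ± 5.72 (exact p = 1) and tRNA 12.2% ± 0.867 and 12.9% ± 1.69 (exact p = 0.7). Both classes hold nuclear IDs only, since organelle IDs of any type were counted as mitochondrial or chloroplast features.

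**Figure D1:**
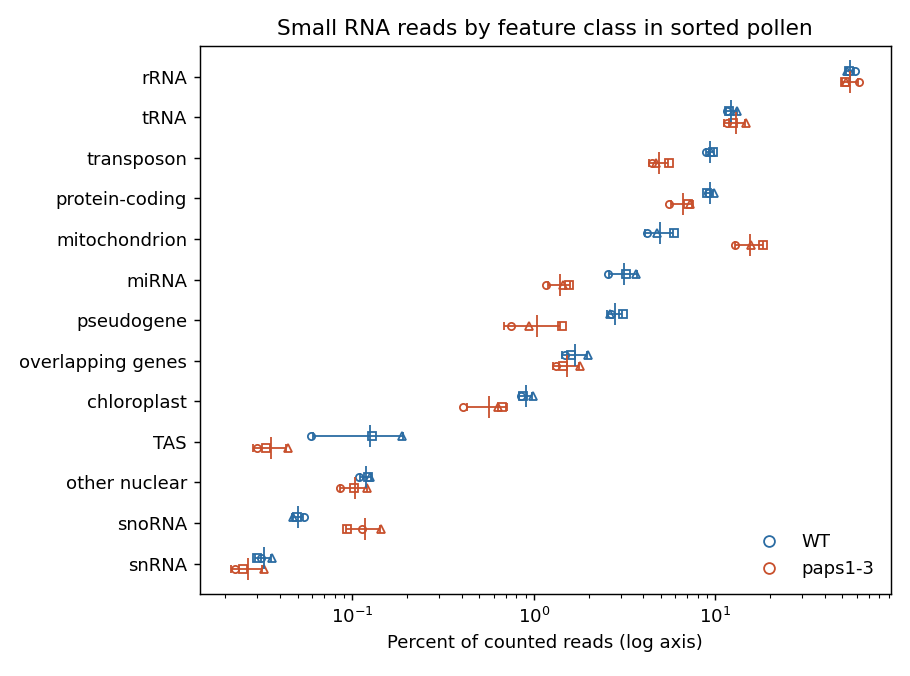
Percent of counted reads by feature class in each of the 6 libraries (points), with the mean and SD per genotype. The transposon, miRNA and TAS points of paps1-3 lie below those of wild type, and the mitochondrial and snoRNA points lie above. The TAS class leaves out TAS1C.

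Among nuclear reads outside rRNA, tRNA, snRNA and snoRNA the contrast was smaller. Transposons then held 35.2% ± 1.2 in wild type and 31.5% ± 2.43 in paps1-3, a ratio of 0.894, and miRNA loci 11.8% ± 1.46 and 8.90% ± 0.163, a ratio of 0.753 (SD, n = 3 each, exact permutation p = 0.1 for both). TAS loci, again without TAS1C, held 0.464% ± 0.220 and 0.230% ± 0.0389, a ratio of 0.496, and their libraries overlapped (exact permutation p = 0.2). Protein-coding genes turned direction, with 35.1% ± 1.61 and 42.4% ± 1.91, a ratio of 1.21.

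Transposon reads were lower in paps1-3 at every length from 18 to 24 nt. In RPM, scaled to all counted reads, 24-nt transposon reads were 16080 ± 1214 in wild type and 7281 ± 532 in paps1-3 (SD, n = 3 each, ratio 0.453). At 21 nt, the length of epigenetically activated siRNAs in pollen, they were 14556 ± 1859 and 7150 ± 1411 (ratio 0.491), and at 22 nt 12732 ± 1923 and 6593 ± 1427 (ratio 0.518). The ratios at 18, 19, 20 and 23 nt were 0.574, 0.525, 0.509 and 0.499. Whether the ratio differed between lengths was not tested. miRNA reads of 21 nt were 18479 ± 1830 and 8738 ± 1202 RPM, and those of 20 nt 8771 ± 2552 and 3075 ± 519. Mitochondrial reads were higher at each length, with ratios from 1.49 at 26 nt to 7.53 at 18 nt, where they were 2922 ± 1674 and 22001 ± 6336 RPM. The libraries of the genotypes did not overlap at any of these lengths (exact permutation p = 0.1). Those for transposons overlapped at 25 to 28 nt (exact permutation p = 0.2 to 0.9).

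**Figure D2:**
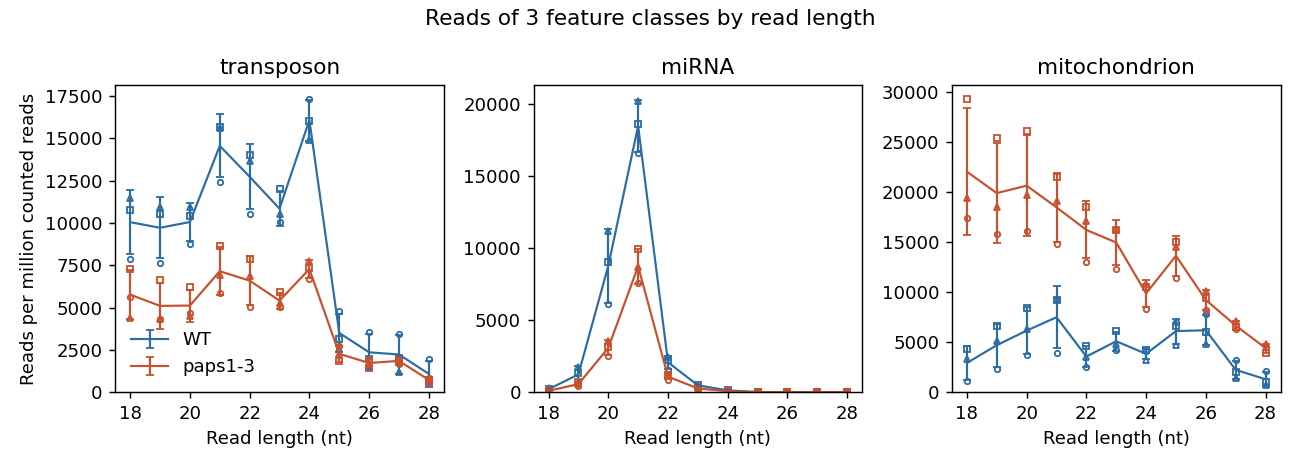
RPM over all counted reads (y axis) by read length in nt (x axis) for transposons, miRNA loci and mitochondrial features, with the mean and SD per genotype as lines and bars and the 3 libraries of each as points. Wild-type transposon reads peak at 21 nt and 24 nt, with 14556 and 16080 RPM, where all paps1-3 points lie below them.

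Tested feature by feature, more features rose than fell in paps1-3. Of 13464 features tested over all lengths, 1921 were higher and 537 lower at an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg, n = 3 per genotype). Protein-coding genes made up most of the higher calls, with 1371 higher and 228 lower of 5496. snoRNA genes rose nearly as a class, with 54 of 61 higher and a median log2 fold change of 1.97 (43 higher with total-read scaling). Mitochondrial features did likewise, with 56 of 76 higher and a median of 2.15 (46 higher and 5 lower with total-read scaling). Of 583 tRNA genes 220 were higher, but with total-read scaling 90 were higher and 54 lower, and many have near-identical copies whose reads cannot be told apart. Transposons had more lower than higher calls, with 67 higher and 265 lower of 6364 and a median of −0.34. The lower calls were 4.16% of tested transposons, near the 3.99% of all tested features. With TMM, what set transposons apart was few higher calls, 1.05% against 14.3% of all tested features. With total-read scaling the lower calls set them apart too, at 3713 of 6364 transposons against 5426 of all 13464 features.

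The counts depended on how the libraries were scaled, because the median of all features was −0.15 with TMM, −0.94 with total counted reads and 0.23 with scaling to miRNA loci. With total reads, 811 features were higher and 5426 lower, including 3713 transposons and 1345 protein-coding genes lower and 534 protein-coding genes higher. With miRNA scaling, 2944 features were higher and 182 lower, and transposons turned to 139 higher and 58 lower. Relative to the median of all features, which takes out a shift common to all features, the TMM-scaled median was −0.20 for transposons, 0.46 for protein-coding genes, 2.30 for mitochondrial features and 2.12 for snoRNA genes. With the isolation as a block, the lower calls grew from 537 to 1154, the lower transposons from 265 to 619, the lower protein-coding genes from 228 to 447 and the higher tRNA genes from 220 to 423.

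Single libraries moved the lower calls. Without paps1-3 26, 1549 features were called, 147 of them lower, and 53 transposons were lower. Leaving out wild-type 25, paps1-3 16 or paps1-3 20 gave 301, 309 and 267 lower features, with 121, 121 and 127 transposons, and leaving out wild-type 19 gave 108 lower transposons. The lower protein-coding genes were 149, 116 and 80 without wild-type 25, paps1-3 20 and paps1-3 26, and the higher tRNA genes 406 and 133 without wild-type 15 and wild-type 19.

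**Figure D3:**
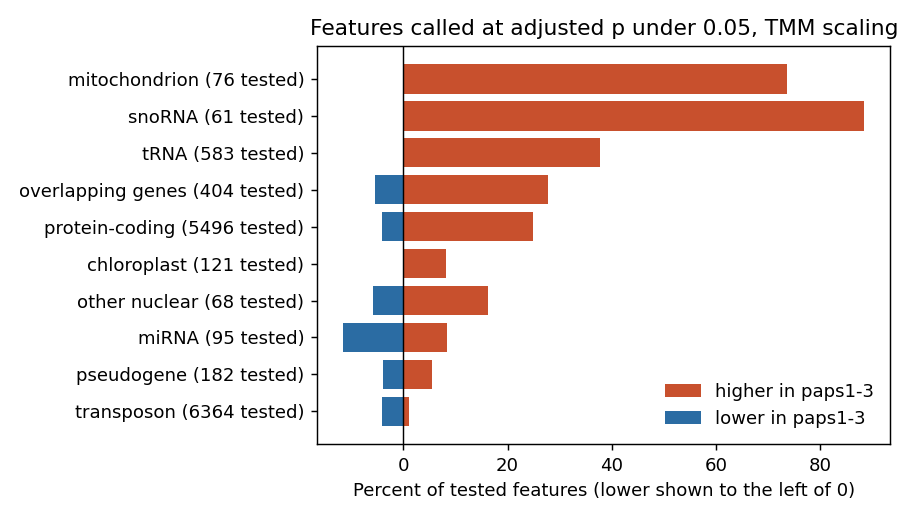
Features called higher or lower in paps1-3 (edgeR, adjusted p of 0.05) in each class with at least 50 tested, as a percent of those tested, with lower calls left of 0. snoRNA and mitochondrial features were mostly higher, 88.5% and 73.7% of those tested, while 4.16% of transposons were lower and 1.05% higher with TMM scaling; total-read and miRNA scaling moved that transposon split to 3713 lower and 31 higher, and to 58 lower and 139 higher.

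The features with the largest increases included 8 protein-coding genes, 2 tRNA genes and 2 mitochondrial features. Small RNA reads on PR5, a pathogenesis-related protein of the thaumatin family, rose from 0.691 ± 0.270 to 14.4 ± 4.11 CPM (log2 4.34, SE 0.33, edgeR adjusted p = 1.52e-05, n = 3 each). The late embryogenesis abundant genes AT5G53820 and AT4G13230, of a family linked to desiccation tolerance, rose by 4.27 and 4.19 on the log2 scale. AT3G28770, of the DUF1216 family, rose by 4.30, the self-incompatibility S1 family gene AT2G04115 by 4.34, the ARM repeat gene AT5G18340 by 4.19 and the lipid-transfer family gene AT3G59455 by 4.18. AT1G28135 rose by 4.54, from 304 ± 219 to 7053 ± 1123 CPM. The mitochondrial ATMG00030 rose by 4.33, from 917 ± 586 to 18396 ± 2936, and a further mitochondrial feature by 4.33. The tRNA genes AT2G07794 and AT2G07752 (4.24 each) belong to the nuclear insertion of mitochondrial DNA on chromosome 2, so their reads cannot be told apart from mitochondrial ones.

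The largest decreases were on 9 protein-coding genes, 2 segments shared by neighbouring genes and 1 transposon. Reads on SP1L4 (AT5G15600), of the family of the microtubule-associated SPIRAL1, fell by 2.65 on the log2 scale, from 33.2 ± 6.02 to 5.31 ± 0.863 CPM (SE 0.25, edgeR adjusted p = 3.41e-05, n = 3 each). Reads on the RALF-like peptide genes RALFL4 and RALFL26 fell by 2.25 and 2.1; RALFL4 acts in pollen tube integrity. PTEN1, a pollen phosphatase gene, fell by 2.12, and the segment it shares with AT5G39410 fell by 2.26. Also lower were PAB8, which encodes a poly(A)-binding protein (−2.25), the cell death regulator LSD1 (−2.06), the sphingolipid desaturase gene SLD2 (−2.02), AT3G26934 (−3.18) and the segment shared by AT3G61160 and AT3G61170 (−2.28). The transposon AT2TE15525 fell by 3.20. AT4G07666 fell by 3.10 (edgeR adjusted p = 0.0107), a call lost without paps1-3 26 (edgeR adjusted p = 0.0873). Strand was not used here, so reads of a gene and of a transcript antisense to it cannot be separated.

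Among vegetative-cell genes of pollen, 2 of the 5 tested rose and 1 fell (2 and 1 adjusted over the list alone). VEX1 (AT5G62850, a sugar transporter gene) rose from 1.27 ± 0.309 to 6.56 ± 1.81 CPM (log2 2.37, SE 0.31, edgeR adjusted p = 0.000235), and the pectin methylesterase gene PPME1 from 85.6 ± 4.20 to 261 ± 39.0 (log2 1.61, SE 0.29, adjusted p = 0.00221, n = 3 each). PTEN1 was the member that fell, and with total-read scaling AT5G45880 did too (−1.02, edgeR adjusted p = 0.00676; −0.23, not called, with TMM). VGD1, a pollen pectin methylesterase gene with the most reads of the list, had 865 ± 121 and 1074 ± 113. Of 5 tested sperm-cell genes, DAZ2, a zinc-finger regulator of sperm development, fell by 1.95 (SE 0.38, edgeR adjusted p = 0.00357), and HAP2, needed for gamete fusion, and GEX1 did not pass (0.58 and 0.41). Adjusted over the list alone, DAZ2 was again the one call. The list's median was 0.41 and its mean −0.04. camera called neither list (adjusted p = 0.731 for vegetative and 0.933 for sperm).

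Markers of other cells gave little signal. None of the 7 tapetum genes passed the count filter, and 3 of 14 leaf photosynthesis genes did. CAB1, RBCS1A and RBCS3B had log2 fold changes of −0.74, 0.08 and −0.06, none called with TMM by edgeR, or by DESeq2 or limma-trend, or adjusted over the list alone, and 1 at an unadjusted p of 0.05 (camera adjusted p = 0.731, list mean −0.24, median −0.06, and 0.09 relative to all features). With total-read scaling CAB1 was called lower (−1.48, edgeR adjusted p = 0.0129). Of the 19 small RNA pathway genes 10 were tested and none was called with TMM by edgeR, also adjusted over the list alone, or by DESeq2 or limma-trend, with 0 at an unadjusted p of 0.05. MET1, the maintenance DNA methyltransferase gene, had −0.39, DCL1, the miRNA-processing Dicer gene, 0.36, AGO9 −0.47 and AGO2 −0.19 (camera adjusted p = 0.747). With total-read scaling 5 of the 10 were called lower, namely MET1 (−1.17), AGO2 (−1.06), AGO9 (−1.30), AGO1 (−0.88) and NRPE1 (−1.26), at edgeR adjusted p of 0.0134 to 0.0321, and with miRNA scaling DCL1 was called higher (0.71, edgeR adjusted p = 0.0424). Of the poly(A) polymerase genes only PAPS4 (nPAP) passed the filter. Its log2 fold change of 0.27 was not called by edgeR, DESeq2 or limma-trend, at an unadjusted p of 0.05 or adjusted over the list alone.

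miRNA loci moved in both directions. Over all lengths 9 of 105 tested loci rose and 12 fell (9 and 13 adjusted over the list alone; 13 and 30 with the isolation as a block), and camera did not call the list (adjusted p = 0.496). In the miRNA class 8 of 95 rose and 11 fell with TMM, against 3 and 43 with total reads and 15 and 9 with miRNA scaling. MIR398c, whose miRNA targets copper/zinc superoxide dismutase messengers, rose from 6.87 ± 3.14 to 54.0 ± 12.3 CPM (log2 2.96, SE 0.35, edgeR adjusted p = 0.000124, n = 3 each), and MIR398b, in a segment shared with AT5G14550, rose by 2.95. MIR827, which acts in phosphate homeostasis, fell by 1.85 (SE 0.26, adjusted p = 0.000429). MIR158a, with the most reads, had 4217 ± 1380 and 3507 ± 643 (−0.27, not called; −1.14 and called with total reads, edgeR adjusted p = 0.0136). The pollen miR845 loci, whose miRNAs match retrotransposon primer-binding sites, were not called with TMM by edgeR, also adjusted over the list alone, or by DESeq2 or limma-trend: MIR845a had 0.01 and MIR845b −0.39, with 0 at an unadjusted p of 0.05 (camera adjusted p = 0.747). With total-read scaling both were called lower, at −0.86 and −1.23 (edgeR adjusted p = 0.0277 and 0.00269), as were MIR845b at 21 nt (0.0216) and both at 22 and 24 nt. At 22 nt MIR845b had −0.55 and was called with the isolation as a block (edgeR adjusted p = 0.0470), but not without it (0.158). Without wild-type 15 the miRNA list was called lower (camera adjusted p = 0.00455).

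At 21 nt, the main length of mature miRNAs, 11 of 88 tested loci rose and 18 fell (11 and 20 adjusted over the list alone; 13 and 25 with the isolation as a block; camera adjusted p = 0.200, but 0.000891 without wild-type 15). Of those in the miRNA class, 10 rose and 17 fell, against 5 and 31 with total reads, 15 and 9 with miRNA scaling, and 4 and 9 without paps1-3 26, and 9, 10 and 8 fell without wild-type 19, paps1-3 16 and paps1-3 20. The following loci were chosen after their values were seen. Besides MIR398b and MIR398c, at 2.94 and 2.91, the loci MIR163 (2.41), MIR393b (1.99), MIR319a and MIR319b (1.89 and 1.86) and MIR172c and MIR172d (1.74 and 1.5) rose. Of the same families MIR172a (−1.14), MIR172b (−0.45) and MIR319c (0.49, but −0.055 with total reads) were not called, though MIR172a was called lower with total reads and with the isolation as a block (edgeR adjusted p = 0.0268 and 0.0208). miR393 targets auxin receptors, miR319 TCP genes and miR172 AP2-type genes. MIR162a (−2.07), MIR827 (−1.99), MIR399a (−1.41), and the 6 loci MIR156a to MIR156f (−1.78 to −1.48) fell. miR162 targets DCL1, and miR156 SPL genes. MIR399c, of the family of MIR399a, stood at 0.96 and was not called (edgeR adjusted p = 0.199). MIR166a to MIR166g fell by 1.06 to 1.0, but with miRNA scaling their edgeR adjusted p was 0.0758 to 0.119. MIR162b, at −0.99, likewise had 0.151. MIR319a, MIR172d and MIR398a missed the threshold with total-read scaling (edgeR adjusted p = 0.0574, 0.0516 and 0.0586), and MIR773a (1.06) and MIR843 (0.97) did so with total reads (0.221 and 0.247) and with RLE factors (0.0565 and 0.0515). None of the called loci changed sign with total-read or miRNA scaling. Loci of one family can share reads, so family members are not independent.

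**Figure D4:**
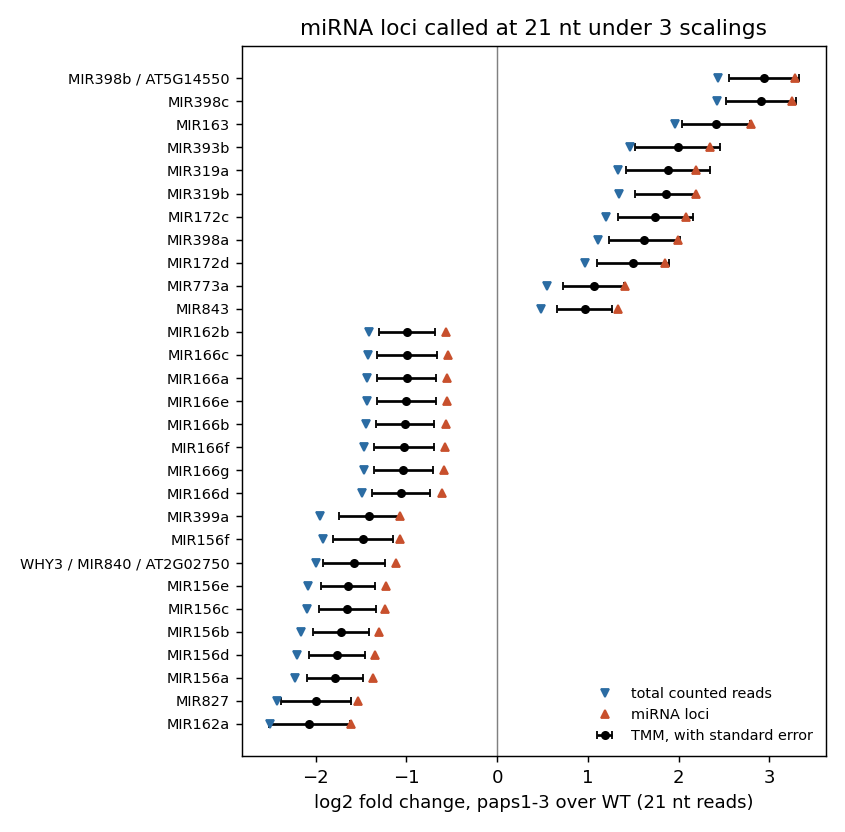
log2 fold change of 21-nt reads, paps1-3 over wild type, with SE, for the miRNA loci called by edgeR with TMM scaling (black points and bars, n = 3 libraries per genotype), with the values under total-read and miRNA scaling as triangles. MIR398b lies highest, at 2.94, and MIR162a lowest, at −2.07, and every locus shown keeps its sign under all 3 scalings.

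At 22 nt, of 50 tested miRNA loci 1 rose and 14 fell (2 and 16 adjusted over the list alone), with a median of −0.68 (camera adjusted p = 1.34e-05, and adjusted p = 0.0300 with an estimated correlation). When the libraries were split 3 against 3 without regard to genotype, camera with the preset correlation also called lists in 3 of the 9 other splits. Loci of one family can share reads, which a low preset correlation does not allow for. Relative to all features the list's median was −0.51, but 0.082 without the count filter (camera adjusted p = 0.00113). With miRNA scaling 4 loci of the miRNA class rose and 8 fell, and with total reads 0 rose and 22 fell. With the isolation as a block 4 rose and 21 fell, and without paps1-3 26 the lower calls in the miRNA class went from 12 to 5. At 24 nt 1 of 16 rose and 3 fell (1 and 5 adjusted over the list alone; 1 and 5 with the isolation as a block; camera adjusted p = 0.214), and 9 of the miRNA class fell with total reads in place of 2.

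TAS loci had fewer 22-nt reads in paps1-3. All 4 tested at that length fell, also when adjusted over the list alone: TAS2 by 1.36 (SE 0.25, edgeR adjusted p = 0.00122), TAS1B by 1.37, TAS1A by 1.22 and the segment of TAS1C shared with AT2G39670 by 1.2. With miRNA scaling TAS1A and TAS1C missed the threshold (edgeR adjusted p = 0.0543 and 0.0803). camera called the list (adjusted p = 0.000852), but not with an estimated correlation (adjusted p = 0.328). At 21 nt, TAS1B (−1.06) and TAS1C (−0.95) fell, while TAS2 (−1.08), TAS1A (−0.74) and TAS3 (−0.41) did not pass; 3 of the 5 passed adjusted over the list alone, and TAS2 with the isolation as a block (adjusted p = 0.00297; camera adjusted p = 0.0953). At that length 4 passed with total reads, while TAS1B and TAS1C missed the threshold with miRNA scaling (edgeR adjusted p = 0.0624 and 0.168). Over all lengths none of the 5 tested was called with TMM by edgeR, against 1 by DESeq2, 1 by limma-trend and 3 at an unadjusted p of 0.05 (1 lower adjusted over the list alone; camera adjusted p = 0.376). TAS1B stood at −0.98 with an edgeR adjusted p of 0.0512 and TAS2 at −1.0 with 0.102. With the isolation as a block both were called, at adjusted p = 0.00257 and 0.0195. With total reads 4 were called lower, TAS1B (−1.86), TAS2 (−1.87), TAS1C (−1.75) and TAS1A (−1.66), at edgeR adjusted p of 0.000352 to 0.0104, and TAS1B passed with RLE factors (0.04997) and without structural and organellar features (0.0457). Without wild-type 15 the list was called over all lengths (camera adjusted p = 0.00284) and at 21 nt (0.000891). At 24 nt none of 4 was called with TMM by edgeR, also adjusted over the list alone, or by DESeq2 or limma-trend, with 1 at an unadjusted p of 0.05 and TAS1A called with the block (−0.99, adjusted p = 0.0152; camera adjusted p = 0.214), and with total reads all 4 were lower.

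Of transposons tested by length, 28 of 1229 rose and 24 fell at 21 nt, 28 of 1469 rose and 19 fell at 22 nt, and 23 of 2186 rose and 151 fell at 24 nt (edgeR, adjusted p of 0.05). The lower calls were 1.95%, 1.29% and 6.91% of the transposons tested, against 4.68%, 4.05% and 6.23% of all features tested at these lengths. With the isolation as a block, 138 were lower at 21 nt, 149 at 22 nt and 204 at 24 nt. Whether the effect differed between lengths was not tested, and simulated 2-fold changes were recovered more often at 24 nt (61%) than at 21 nt (21%). Across 1053 transposons tested at both lengths, the log2 fold changes at 21 and 24 nt had a Pearson r of 0.23 and a Spearman rho of −0.02, while across 570 protein-coding genes these were 0.93 and 0.91. Features are not independent replicates. With total-read scaling 454 transposons fell at 21 nt, 360 at 22 nt and 1546 at 24 nt, and with miRNA scaling 8, 4 and 129. Leaving out wild-type 19, wild-type 25, paps1-3 16, paps1-3 20 or paps1-3 26 gave 81, 79, 49, 98 and 23 lower 24-nt transposons. At 21 nt 68 were lower without wild-type 15, and 11, 13, 12 and 10 without wild-type 19, paps1-3 16, paps1-3 20 and paps1-3 26. At 22 nt 87, 10, 6 and 3 were lower without wild-type 15, wild-type 19, paps1-3 20 and paps1-3 26.

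Over all classes, 462 features rose and 149 fell at 21 nt of 3181 tested, 414 and 131 of 3231 at 22 nt, and 603 and 224 of 3593 at 24 nt (edgeR). With the isolation as a block, 1063 features were called at 21 nt and 971 at 22 nt, in place of 611 and 545. Without wild-type 15 the totals were 1030 and 896, and without paps1-3 26 they were 362 and 312, with 489 at 24 nt in place of 827.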

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

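Of 2361 values recomputed under an alternative, 1929 were scored as the same. For tests this meant the same direction and side of the threshold, and for class shares and PAPS1 the same direction. For counts it meant a change of at most 1.5 times, and for medians a shift within a fixed limit on the log2 scale. These limits are not measures of sampling error. Of the rest, 334 counts or medians moved further, 34 tests gained and 2 lost a call, and 62 values turned direction. The 30 called features that the rule for named genes took over all lengths kept sign and call in 475 of their 476 alternatives; AT4G07666 lost its call without paps1-3 26. The report gives the called 21-nt miRNA loci that missed the threshold under another scaling. PAPS1 kept its direction in all 7. Class shares kept theirs in 126 of 136. Unless a cause is named, the cause was not tested. The fits without libraries 15 and 16 and the shares without mitochondrial reads were added after seeing the data. Lists have no value under DESeq2 or limma-trend, since camera uses log-CPM. Transposon superfamilies and locations were not run.

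Features changed in paps1-3 pollen, 2458 in the fit as planned (1921 higher, 537 lower), were 6237 with total reads (811 and 5426), and 2944 higher and 182 lower with miRNA scaling. Their lower calls were 287 with DESeq2. The replicate block, using the pairing of adjacent numbers, gave 3684 calls, 2449 of them shared with the fit without it, and 1154 lower; at 21 nt it gave 1063 (710 higher, 353 lower) and at 22 nt 971 (363 lower). Of the genes that the rule took over all lengths, it changed the calls of TAS1B and TAS2 and no other. Leaving out 1 library in turn gave 1549 to 3135 calls and 147 to 408 lower ones. The lists called numbered 0 to 2 over all lengths and at 21 nt, and 2 without libraries 15 and 16 at each.

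At 21 nt (611 calls, 462 higher, 149 lower) the calls were 1081 with total reads (785 lower, 296 higher), 812 higher and 71 lower with miRNA scaling, 344 without filter (242 higher), 2 lists without filter, and 921 without libraries 15 and 16 (743 higher). Leaving out 1 library gave 362 to 1030 (293 to 809 higher, 69 to 221 lower). At 22 nt (545, 414 and 131) they were 894 with total reads (216 and 678), 61 lower with miRNA scaling, 325 without filter (234 higher), 87 lower with DESeq2, 319 without structural and organellar features (252 and 67), 837 without libraries 15 and 16 (629 and 208), and 312 to 896 with 1 library left out (274 to 679 and 38 to 217). With an estimated correlation 1 list was called at 22 nt. At 24 nt (827, 603 and 224) they were 2256 with total reads (300 and 1956), 105 lower with DESeq2, 460 without structural and organellar features (343 and 117), and 489 to 981 with 1 library left out (50 to 263 lower).

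Fixed lists that turned direction, as medians relative to all features: sperm cell 0.53 with total reads, 0.54 with miRNA scaling and 0.36 to 0.70 with 1 library left out, where the test and the median differ in sign; leaf photosynthesis −0.14 with the stricter filter, −0.14 without structural features, −0.28 without libraries 15 and 16, and −0.56 to −0.038; small RNA pathway −0.014 without structural features, −0.030 without libraries 15 and 16, and −0.080 to 0.071; miRNA loci 0.11 without filter and −0.29 to 0.10; miR845 0.16 without filter and −0.17 to 0.15. Without filter, miRNA loci stood at 0.093 at 21 nt (−0.32 to 0.094 with 1 library left out), 0.082 at 22 nt and 0.29 at 24 nt, and TAS loci at 0.49 at 24 nt.

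Named genes that turned sign were all uncalled in the fit as planned. With total reads these were RBCS1A −0.71, VGD1 −0.48, HAP2 −0.23, GEX1 −0.40, DCL1 −0.46, nPAP −0.52 and MIR845a −0.86, and with miRNA scaling RBCS3B 0.34, AGO2 0.17 and MIR158a 0.10. MIR845a was −0.0025 without filter and −0.20 without libraries 15 and 16, and RBCS3B 0.047 without structural features and 0.51 without libraries 15 and 16. With 1 library left out, RBCS3B ran from −0.66 to 0.43, MIR845a from −0.12 to 0.21, RBCS1A from −0.21 to 0.45, AGO2 from −0.28 to 0.025 and MIR158a from −0.36 to 0.000234.

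Class shares that turned, as ratios of paps1-3 to wild type, were 1.21 for protein-coding genes, 1.54 for overlapping genes and 1.47 for other nuclear features with structural and organellar reads left out, 1.05 for other nuclear features without their most counted one, and 1.02 for overlapping genes and 1.12 for rRNA without mitochondrial reads. With 1 library left out rRNA ran from 0.938 to 1.03 and tRNA from 0.978 to 1.11.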

Other observations

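The tests in this part were chosen after the results were seen, except the counts of other splits and the read-length test on protein-coding genes. Among protein-coding genes with a shared product, 8 groups were tried, also chosen after their values were seen (one-sided Fisher exact tests against the 5496 tested genes, Benjamini-Hochberg over both directions). The groups were picked from these same calls, and genes of a group may share reads. The p-values therefore describe the groups and cannot support an enrichment. Of the late embryogenesis abundant genes 11 of 15 were called higher and 1 lower (Fisher adjusted p = 0.000882), and with total-read scaling 9 higher and 3 lower. AT1G52680 rose from 3.8 ± 1.75 to 64.3 ± 5.35 CPM (SD, n = 3 each), AT3G02480 by 4.0 on the log2 scale and UNE15 by 3.01. Of the DUF1216 genes 8 of 10 were higher (adjusted p = 0.00192; with total-read scaling 7 higher), among them AT3G28840 (4.10) and AT5G39870 (3.89). Of the cation/H+ exchangers 9 of 14 were higher and 1 lower (Fisher adjusted p = 0.00669, and 0.104 with miRNA scaling), with CHX19 at 3.79 and CHX23 at −1.08. Cytosolic ribosomal protein genes, with 5 of 44 higher, 8 with the isolation as a block and 13 with miRNA scaling, were not enriched (adjusted p = 1 in each). RALF-like genes, with 5 of 12 higher and 2 lower, were not enriched with TMM (adjusted p = 0.313 and 0.197), but with total-read scaling 5 were higher at adjusted p = 0.0101 and 5 lower.

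Pentatricopeptide repeat genes, which include known targets of TAS2-derived siRNAs, had 8 of 34 lower and 3 higher (Fisher adjusted p = 0.000882). The 8 were AT1G62590, AT1G62910, AT1G62914, AT1G63070, AT1G63080, AT1G63320, AT1G63330 and AT1G63400, at log2 −1.67 to −0.77. Of their wild-type reads 57.5% ± 0.952 were 21 nt long (SD, n = 3), and 55.0% ± 4.47 in paps1-3. All 8 have IDs from a single stretch of chromosome 1, and genes of a family can share reads. The Fisher test treats them as independent, so its p-value may count the same reads several times. With total reads 17 of the 34 were lower and 2 higher. With miRNA scaling 2 were lower and 7 higher (Fisher adjusted p = 0.294). Pectin methylesterase and inhibitor genes had 7 of 35 lower and 5 higher (adjusted p = 0.00192), 21 and 3 with total reads, and 4 and 7 with miRNA scaling (adjusted p = 0.0250). Protein kinase genes had 10 of 102 lower and 20 higher (adjusted p = 0.0248), and 35 and 6 with total reads. The protein kinase group missed the threshold with RLE, where 8 were lower (Fisher adjusted p = 0.0842). It also did so with miRNA scaling, where 5 were lower and 36 higher (0.104), and with the isolation as a block, where 11 were lower (0.468).

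Mitochondrial reads were 3.15 times as large a share in paps1-3. Breakdown of organellar RNA in general would raise the chloroplast share too. Among reads outside mitochondrial features that share had a ratio of 0.711 (log2 −0.53, SE 0.26). A share can also fall by dilution, and the direction of chloroplast features depended on the scaling. With TMM 10 of 121 were called higher and 0 lower (median log2 0.005). With total reads 3 were higher and 55 lower (median −0.81, edgeR). The test therefore cannot decide on general breakdown. ATMG00020 alone held 8.38 of the 10.6 percentage points, and ATMG01390 and ATMG00030 rose by 2.22 and 1.26. Most of the rise in share thus lay in a few features. A few features as the whole cause are argued against by the ratio without the 4 most counted, which include the falling ATMG00270. It was 1.80 (0.489% ± 0.0146 and 0.881% ± 0.142, SD, n = 3 each), and 1.38 without the 5 most counted, with no overlap of libraries in either. Feature by feature, 46 of 76 were called higher with total reads (edgeR), which also argues against a few features as the whole cause. Damage to mutant grains during the sort, a difference between gates and an effect of PAPS1 on mitochondrial RNA stay open, because genotype and gate are the same split. General breakdown of organellar RNA stays open as well.

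The lower transposon and miRNA shares may be dilution by other reads. Without mitochondrial reads the ratios were 0.593 (log2 −0.76, SE 0.13) and 0.500 (log2 −1.0, SE 0.22), so mitochondrial reads were not the whole cause. Among nuclear reads outside rRNA, tRNA, snRNA and snoRNA they were 0.894 (log2 −0.16, SE 0.07) and 0.753 (log2 −0.40, SE 0.11), with no overlap of libraries. For miRNA loci this argues against dilution by structural and organellar reads as the whole cause. Most of the transposon difference went with those reads, and for transposons the test cannot decide. The remaining difference was more than 2 SE from 0, but its size depends on what the nuclear total keeps. That total kept AT1G28135, with 1534, 7315 and 3118 reads in wild type and 32634, 37484 and 50613 in paps1-3. It also kept AT2G07731, whose reads cannot be told apart from those of the mitochondrial ATMG00270. AT2G07731 held 2.41% of all counted reads in wild type and 0.782% in paps1-3. Keeping these features moves the transposon ratio in opposite directions. Whether the libraries stay apart without these features was not tested. A lower yield of small RNA per grain, more breakdown fragments per grain and less transcription into siRNA precursors in paps1-3 stay open.

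Reads on the 1371 higher protein-coding genes may be breakdown fragments of messenger RNA rather than Dicer products. Before the result was seen, the prediction was a percent of 21-nt and 24-nt reads no higher than that of rRNA in every paps1-3 library. It was 18.7% ± 0.579 (SD, n = 3), against 20.2% ± 1.28 for rRNA, 29.5% ± 1.64 for transposons and 63.4% ± 2.44 for miRNA loci, and below rRNA in all 3 libraries. Without the most counted gene it was 19.5% ± 0.636, and paps1-3 20 then lay above its rRNA, at 19.2% against 18.8%. Whether such fragments came from higher messenger levels or from faster decay in paps1-3 was not tested.

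The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 2458 features over all lengths, 611 at 21 nt, 545 at 22 nt and 827 at 24 nt, each the count of 1 split, and the highest other split called 0. Of the 9 other splits 3 also part all 3 isolations. All 9 mix the genotypes, so a genotype difference widens the spread within their groups and leaves few calls. For the lists the real split called 0 over all lengths, 0 at 21 nt, 2 at 22 nt and 0 at 24 nt, and the highest other split 2, 2, 2 and 1, so that 10, 10, 2 and 10 splits called as many. A count of 0 is matched by every split whatever its values, so those comparisons carry no information.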
